A study of Mus musculus with 60 samples.

How the data were processed

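RNA was measured in 60 libraries from female NOD/ShiLtJ mice with experimental autoimmune encephalomyelitis, a model of chronic inflammatory demyelination. The labels give 3 cell types sorted from brain and spinal cord (astrocytes, microglia and monocytes) and 5 treatments, with 4 libraries in each of the 15 groups. The treatments are Vehicle, empty liposomes (Plain_L), liposomes carrying ITE, a ligand of the aryl hydrocarbon receptor (ITE_L), liposomes carrying a myelin oligodendrocyte glycoprotein peptide (MOG_L), and liposomes carrying both (ITE_MOG_L). Libraries were made with Smart-seq2, a full-length protocol for low RNA input. Replicates are numbered here in the order of the series. The labels name no animal, so it is not known whether the 4 libraries of a group come from 4 mice, and all p-values measure the spread between samples, which may be technical.

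The deposited files give raw counts of fragments per gene name, 1 file per library, with no normalization by the authors. Per the labels, reads were aligned with STAR 2.7.2 to GRCm38, and per the file headers a filtered alignment was counted over exons with featureCounts 1.6.2 and the Ensembl release 96 annotation, in paired mode and with no strand option. The processing notes give Subread 1.5.0 for the same step. What the filter removed is not given in the sources used here. Unstranded counting cannot separate overlapping genes on opposite strands, and reads that several members of a gene family share can move between them.

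Each file held 55418 genes. Total counts ran from 129546 to 1086295 in astrocytes, from 128405 to 1034467 in microglia and from 195959 to 1829793 in monocytes. One count was worth 7.72 CPM (counts scaled to the library total) in the shallowest astrocyte library and 0.921 in the deepest. No library fell below the minimum of 100000 counts. Smart-seq2 reads carry no molecular identifiers, so floors based on counts cover counting error only. A floor of 3 counts over the group was used where a group had no count.

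As a measure of scattered reads, counts on 1442 genes of olfactory, vomeronasal and trace amine-associated receptors, which brain cells are not known to express in quantity, were summed over 5338.9 kb and divided by the total count. Libraries at 2 or more CPM per kb are called high-background libraries. There were 10 of them, and this limit was chosen after the libraries had been seen.

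Within each cell type, edgeR 4.0.16 under R 4.3.3 was fitted to all 5 treatments (filterByExpr, TMM scaling, robust quasi-likelihood F test, 2-sided), and 7 comparisons were tested, 21 in all. A gene counted as past the threshold at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. CPM values use the TMM effective library sizes and are given as mean ± SD, n = 4 libraries. Fold changes are edgeR log2 estimates, with a standard error from the F statistic. A joint fit of cell types and treatments tested in 3 contrasts whether the effect of ITE_MOG_L against Plain_L differed between cell types.

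Before the data were examined, 26 gene lists and 16 lists of cell type markers, the 7 comparisons, the alternatives and the rule for naming genes were fixed. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over all lists and comparisons of a cell type, and again with the correlation estimated for each list. Beside each list stands the number of members past the threshold over all genes and the number when p was adjusted over the list alone. The naming rule took, for each of the comparisons of ITE_MOG_L with Plain_L and with Vehicle, up to 10 rises and 10 falls with the largest fold change among genes past the threshold, with libraries of the groups not overlapping and a mean of at least 5 CPM. It took up to 5 of each in the other comparisons. Members of lists past the threshold followed, and a fixed set around the aryl hydrocarbon receptor and inflammation, whatever its result. Where fewer than 5 genes qualified, the 5 with the smallest p were named as not past the threshold. Genes without a symbol, numbered predicted genes, clones and receptor or immunoglobulin segments were left out of the naming. With 4 against 4 libraries, chance alone separates 2.86% of genes.

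The alternatives were RLE scaling, DESeq2 1.42.0 with its own size factors, limma voom with sample quality weights, no filter on low counts, a fit of the 2 compared groups alone, leaving out shallow libraries, and leaving out each library of the compared groups in turn. DESeq2 was fitted to all genes with a count, without the edgeR filter. For lists they included the estimated correlation and fry, which asks whether a list moves one way without comparing it with other genes. Leaving out high-background libraries was added after the data had been seen, as was a factorial fit of the ITE and MOG loads. Each compared split of 8 libraries was set against all 35 ways of splitting them, or against 50 or 100 drawn splits for larger designs.

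The steps were tested on simulated data with known changes. Of 100 genes changed 4-fold between ITE_MOG_L and Plain_L, 51% were recovered in astrocytes, 60% in microglia and 58% in monocytes, and of those changed 2-fold 4%, 11% and 6%. False calls numbered 4, 1 and 2. For a 4-fold difference in response between monocytes and astrocytes, the only contrast of cell types simulated, 12 of 167 genes were recovered. Libraries carry 2 index sequences, and the second one forms 5 sets that follow the groups. In astrocytes Vehicle, Plain_L and ITE_L share one set and both MOG-carrying groups another. In microglia Plain_L, ITE_L and MOG_L share a set, and in monocytes Vehicle and Plain_L share one and the other groups another. ITE_MOG_L and Plain_L, and ITE_MOG_L and Vehicle, always lie in different sets, so for these comparisons set and treatment cannot be told apart. In astrocytes the same holds for MOG_L against Plain_L and for ITE_MOG_L against ITE_L. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.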

Results

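The series followed gene expression in astrocytes, microglia and monocytes of mice in the chronic phase of experimental autoimmune encephalomyelitis. Liposomes were given weekly from day 35 after induction, and brain and spinal cord were harvested at about day 100. Each of the 15 groups of a cell type and a treatment had 4 libraries. The median total count was 787367 in astrocytes, 575267 in microglia and 1105564 in monocytes.

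Libraries of the same group differed in scattered reads. On receptor genes that brain cells are not known to express in quantity, 4 astrocyte libraries were high: Plain_L replicates 3 and 4 (2.19 and 3.73 CPM per kb), MOG_L replicate 4 (4.83) and ITE_MOG_L replicate 3 (4.26), with the others at 0.908 or below. In microglia Plain_L replicates 1 and 3 (4.01 and 3.57) and ITE_L replicates 1 and 3 (3.65 and 2.57) were high, and the others reached at most 1.24. In monocytes Vehicle replicate 2 (3.28) and ITE_MOG_L replicate 3 (4.6) were high, and the others reached at most 1.54.

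**Figure D1:**
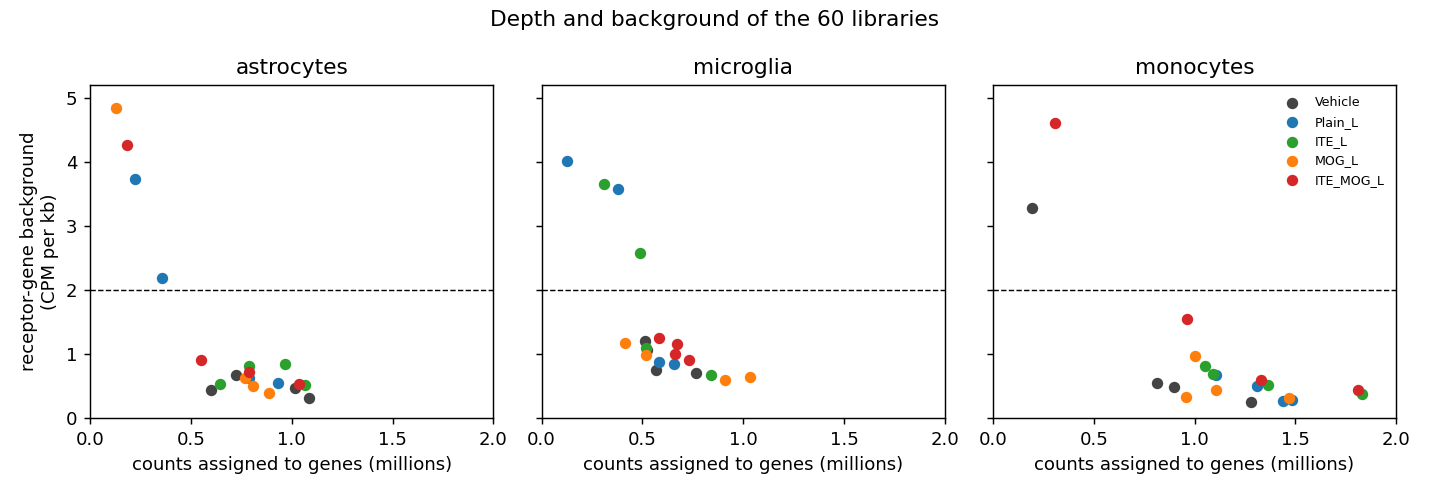
Background on receptor genes (CPM per kb) against the counts assigned to genes, 1 point per library, coloured by treatment, with the dashed line at the limit of 2. The libraries above the line were among the shallower ones of their cell type.

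Marker genes showed what each sorting gate held. The astrocyte markers summed to 4697 ± 1119 CPM in Vehicle astrocytes, against 479 ± 149.6 in microglia and 169 ± 44.5 in monocytes (mean ± SD, n = 4). Microglia markers summed to 24898 ± 4224 CPM in Vehicle microglia and to 10874 ± 5917 in Vehicle monocytes. The astrocyte libraries also carried RNA of other cells: in the Vehicle group oligodendrocyte markers summed to 41086 ± 10069 CPM, ependymal and choroid markers to 21092 ± 5280.2, erythroid markers to 17425 ± 17556 and microglia markers to 3643 ± 1575. Monocyte and macrophage markers summed to 4839 ± 1867 CPM in astrocyte libraries of Vehicle and to 257 ± 88.3 in those of ITE_MOG_L.

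In astrocytes, ITE_MOG_L against Plain_L asked what the loaded liposomes did beyond the empty carrier. In all 39 genes fell and 3 rose. The cytokine gene Il1b lay at 16.4 ± 7.4 CPM in ITE_MOG_L and 208 ± 209 in Plain_L (log2 fold change -3.64, SE 0.786, adjusted p 0.0346, n = 4 each), and Clec7a, a glucan receptor of activated microglia, at 10.8 ± 7.31 and 167 ± 188 (log2 fold change -4.22, SE 0.777, adjusted p 0.0215). The leukocyte integrin gene Itgb2 fell from 103 ± 93 to 7.45 ± 4.3 CPM (-3.8, adjusted p 0.0117) and the B cell chemokine gene Cxcl13 from 76.1 ± 87.3 to 0.972 ± 1.94 (-6.33, adjusted p 0.028). The chemokine gene Ccl6 (-5.91, adjusted p 0.0117) and the neutrophil gene S100a9 (-4.17, adjusted p 0.027) fell; both belong to families whose members can share reads. Grin2c, an NMDA receptor subunit found in astrocytes, rose from 15.6 ± 10.6 to 93.3 ± 16.5 CPM (log2 fold change 2.5, SE 0.457, adjusted p 0.0215), and the synaptic scaffold gene Dlgap1 and the chloride channel gene Ttyh3 rose by 1.81 and 1.39.

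The following 4 lists fell in this comparison at the preset correlation. Of 20 measured genes of NF-kB and inflammatory cytokines 2 fell over all genes and 12 adjusted over the list alone (median -1.59, adjusted p 3.66e-17, and adjusted p = 0.0241 with an estimated correlation). Of 6 NADPH oxidase genes, which serve superoxide production in phagocytes, 1 fell over all genes and 6 adjusted over the list alone (median -2.52, adjusted p 1.08e-10, and adjusted p = 0.0468 with an estimated correlation), with Cyba going from 126 ± 89.4 to 20.6 ± 4.83 CPM. Of 12 complement genes 1 fell over all genes and 8 adjusted over the list alone (median -1.72, adjusted p 6.05e-10, and adjusted p = 0.0468 with an estimated correlation), with the receptor gene C3ar1 going from 71.4 ± 45.1 to 9.01 ± 9.51 CPM. Of 19 antigen presentation genes 0 fell over all genes and 10 adjusted over the list alone (median -1.73, adjusted p 1.85e-13, and adjusted p = 0.115 with an estimated correlation).

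The list of astrocyte homeostasis rose at the preset correlation. Of 18 genes of astrocyte homeostasis 0 rose over all genes and 13 adjusted over the list alone (median 1.42, adjusted p 3.15e-15, and adjusted p = 0.132 with an estimated correlation). Astrocyte markers summed to 6582 ± 3683 CPM in ITE_MOG_L, 2225 ± 1134 in Plain_L and 4697 ± 1119 in Vehicle, with the high-background Plain_L replicate 4 at 953. Aldh1l1, a folate enzyme used as an astrocyte marker, lay at 156 ± 61.7 against 59 ± 17.2 CPM and the growth factor receptor gene Fgfr3 at 674 ± 215 against 205 ± 119 (adjusted p 0.188 and 0.243). Gfap, the filament gene of reactive astrocytes, lay at 37.6 ± 28.4 and 48.3 ± 38.7 CPM (adjusted p 1).

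For ITE_MOG_L against Plain_L in astrocytes 42 genes passed the threshold, 3 higher and 39 lower, and 27 had groups that did not overlap (over all tested genes the share was 3.02%, and chance gives 2.86%). The count was 0 with voom and 0 in a fit of the 2 groups alone, 195 with DESeq2 (65 higher), 114 without the filter, 101 without the shallow MOG_L replicate 4 and 81 without high-background libraries. It was 0, 22 and 0 without ITE_MOG_L replicate 1, 2 and 4, and 4, 13 and 111 without Plain_L replicate 2, 3 and 4. Microglia markers summed to 347 ± 245 CPM in ITE_MOG_L and 1039 ± 816 in Plain_L, and monocyte and macrophage markers to 257 ± 88.3 and 3215 ± 3002. Neutrophil markers summed to 54.9 ± 74.3 CPM in astrocyte libraries of ITE_MOG_L, 128 ± 24.1 in MOG_L, 441 ± 138 in Plain_L, 515 ± 653 in ITE_L and 176 ± 70.5 in Vehicle. The ITE_L libraries ran from 65 to 1486 CPM. The 2 groups lie in different index sets. Of 22 genes named and past the threshold, 0 stayed past it in each of the 8 fits that left out a library of the 2 groups. Without high-background libraries Clec7a, Cxcl13, S100a9, Grin2c and Ttyh3 did not pass, while Il1b, Itgb2, Ccl6, Dlgap1, Cyba and C3ar1 did. Dlgap1 and Ttyh3 did not pass without the filter.

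**Figure D2:**
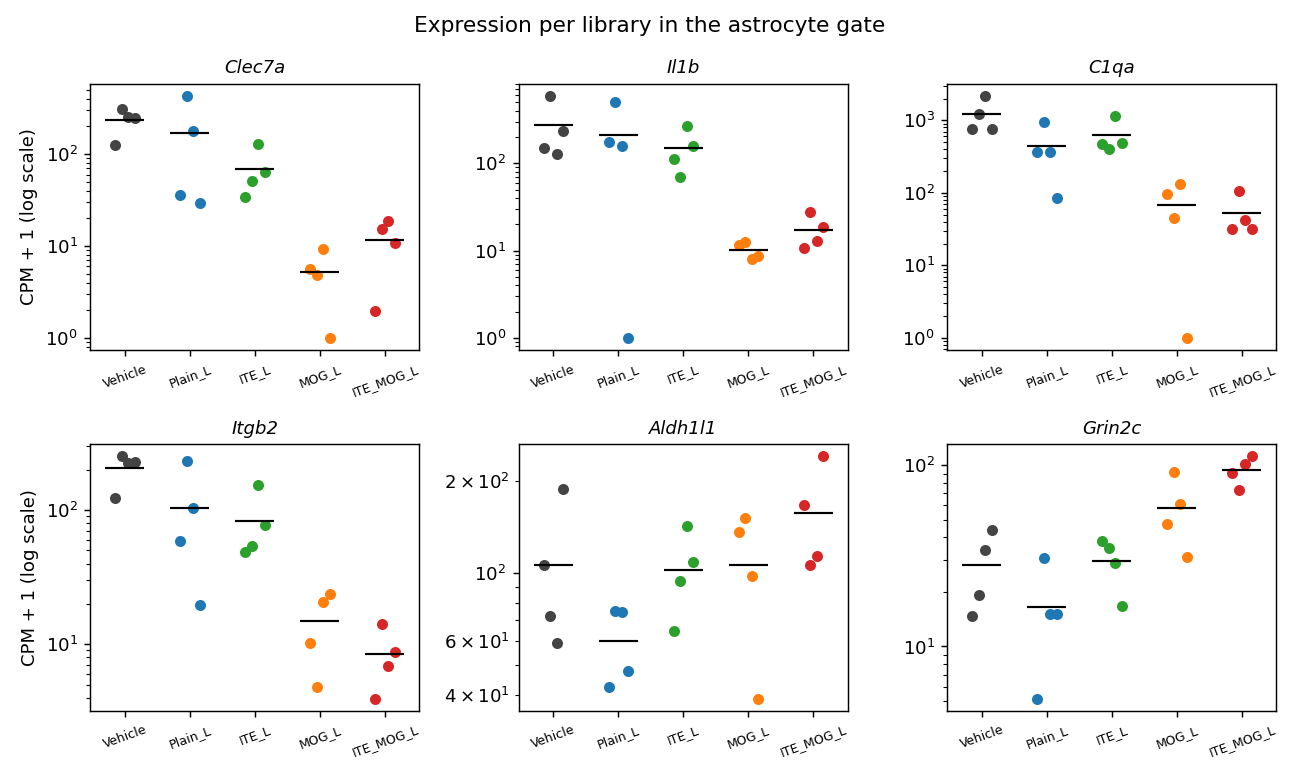
CPM + 1 on a log axis for 6 genes in astrocyte libraries of the 5 treatments, 1 point per library, lines at the mean of 4. Itgb2 averaged 7.45 CPM in ITE_MOG_L and 205 in Vehicle, and Grin2c 93.3 and 27.

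In astrocyte libraries 242 genes were lower in ITE_MOG_L than in Vehicle and 11 were higher. Of the lower ones, 95.9% were at least 4 times higher in microglia or monocyte libraries than in astrocyte libraries. The complement gene C1qa lay at 51.8 ± 35.2 CPM against 1231 ± 675 in Vehicle (log2 fold change -4.55, SE 0.847, adjusted p 0.00241, n = 4 each), the fractalkine receptor gene Cx3cr1 at 44.4 ± 40.6 against 651 ± 279 (-3.84, adjusted p 0.00646) and the microglial membrane gene Tmem119 at 25.7 ± 22.5 against 392 ± 173 (-3.79, adjusted p 0.00118). Spp1, a secreted phosphoprotein, fell from 1697 ± 1791 to 41.4 ± 19.8 CPM (-5.29, adjusted p 0.00581), and Itgb2 (-4.74, adjusted p 0.000406) and Il1b (-4.01, adjusted p 0.00434) fell too. Tumour necrosis factor (Tnf) fell from 75.5 ± 30.7 to 13.3 ± 13.9 CPM (-2.87, adjusted p 0.0336) and the chemokine gene Cxcl10 from 28.8 ± 18.9 to 3.02 ± 2.23 (-2.9, adjusted p 0.0199). The chemokine receptor gene Ccr7 had no count in ITE_MOG_L and was at least 18.7-fold lower than the 22.8 CPM of Vehicle, at a floor of 3 counts over the group. Among rises, the carbonic anhydrase gene Car3 went from 2.26 ± 2.01 to 24.7 ± 10.8 CPM (3.23, adjusted p 0.032), the adhesion receptor gene Adgrb1 from 7.01 ± 2.43 to 30.9 ± 13.5 (2.05, adjusted p 0.029) and Lgi1, a secreted synaptic gene, from 22.4 ± 5.99 to 66.5 ± 15.1 (1.52, adjusted p 0.029).

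Of 17 genes of homeostatic microglia 12 fell over all genes and 13 adjusted over the list alone against Vehicle (median -3.01, adjusted p 1.17e-22, and adjusted p = 0.0318 with an estimated correlation). Of 23 genes of disease-associated microglia 12 fell over all genes and 13 adjusted over the list alone (median -2.46, adjusted p 8.62e-23, and adjusted p = 0.0468 with an estimated correlation). Of 19 antigen presentation genes 8 fell over all genes and 16 adjusted over the list alone (median -2.52, adjusted p 1.32e-20, and adjusted p = 0.0468 with an estimated correlation), with the class II gene H2-Aa, of a family with shared reads, going from 1034 ± 381 to 52.2 ± 76.4 CPM. Of 28 ribosomal protein genes 0 fell over all genes and 0 adjusted over the list alone (median -0.93, adjusted p 2.87e-13, and adjusted p = 0.367 with an estimated correlation). Gfap lay at 37.6 ± 28.4 against 58.6 ± 18.3 CPM (adjusted p 0.799).

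For ITE_MOG_L against Vehicle 253 genes passed the threshold, 11 higher and 242 lower, and 237 had groups that did not overlap (over all tested genes the share was 9.62%, and chance gives 2.86%). The count was 131 without ITE_MOG_L replicate 1, 132 without replicate 4 and 388 without high-background libraries. The median log2 fold change was 0.43 with DESeq2, over all genes with a count, and 0.02 with TMM, over the filtered genes. These medians cover different genes, so their gap cannot be put down to scaling alone. Microglia markers summed to 347 ± 245 CPM in ITE_MOG_L and 3643 ± 1575 in Vehicle, and monocyte and macrophage markers to 257 ± 88.3 and 4839 ± 1867. These groups, too, lie in different index sets. Of 59 genes named and past the threshold, 29 stayed past it in each of the 8 fits that left out a library of the 2 groups, among them C1qa, Itgb2, Il1b, Spp1 and Tmem119. The rises of Car3, Adgrb1 and Lgi1 stayed in 3 of 8, 2 of 8 and 1 of 8 such fits, and the falls of Tnf and Cxcl10 in 4 of 8 and 4 of 8. Tnf did not pass with DESeq2 or without the shallow MOG_L replicate 4, Cxcl10 with voom, or Adgrb1 and Lgi1 without the filter.

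In astrocyte libraries 23 genes were lower in MOG_L than in Plain_L and none was higher. These groups lie in different index sets, so set and treatment cannot be told apart. Clec7a lay at 4.21 ± 3.44 CPM in MOG_L (log2 fold change -5.02, SE 0.823, adjusted p 0.0146, n = 4 each), the cytokine gene Il1a at 3.13 ± 3.33 against 48 ± 31.5 (-3.63, adjusted p 0.0199) and Cybb, the catalytic oxidase subunit, at 18.6 ± 9.45 against 107 ± 59.5 (-2.72, adjusted p 0.0454). Of 20 genes of NF-kB and inflammatory cytokines 2 fell over all genes and 11 adjusted over the list alone (median -1.49, adjusted p 9.67e-12, and adjusted p = 0.0389 with an estimated correlation). The sum of microglia markers was 518 ± 306 CPM in MOG_L and 1039 ± 816 in Plain_L, and that of monocyte and macrophage markers 246 ± 90.3 and 3215 ± 3002. Groups did not overlap in 16 of the 23 genes (over all tested genes the share was 2.5%, and chance gives 2.86%). The count was 89 with DESeq2, 0 in a fit of the 2 groups alone, 97 without the filter and 6 without the shallow MOG_L replicate 4. It was 0, 0 and 0 without MOG_L replicate 1, 2 and 3, and 37, 0, 3 and 87 without Plain_L replicate 1, 2, 3 and 4. Cybb stayed past the threshold in 2 of 8 such fits and in 2 of 7 other settings. Clec7a stayed in 3 of 8 and was lost in the fit of the 2 groups alone and without shallow or high-background libraries. Il1a stayed in 3 of 8 and in 6 of 6 other settings.

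In astrocyte libraries 12 genes were lower in ITE_MOG_L than in ITE_L and none was higher. Here, too, the groups lie in different index sets, and set and treatment cannot be told apart. The microglial gene Aif1 lay at 4.19 ± 3.28 against 59 ± 29 CPM (log2 fold change -3.91, SE 0.704, adjusted p 0.0302, n = 4 each) and the chemokine gene Ccl4 at 15.4 ± 10.1 against 123 ± 66 (-2.93, adjusted p 0.0302). Among lists, of 17 genes of homeostatic microglia 1 fell over all genes and 13 adjusted over the list alone (median -2.32, adjusted p 3.04e-18, and adjusted p = 0.0389 with an estimated correlation). In these libraries microglia markers summed to 347 ± 245 CPM in ITE_MOG_L and 2074 ± 1271 in ITE_L, and monocyte and macrophage markers to 257 ± 88.3 and 1517 ± 663. Groups did not overlap in 11 of the 12 genes (over all tested genes the share was 6.16%, and chance gives 2.86%). The count was 96 with DESeq2, 30 with voom, 26 in a fit of the 2 groups alone, 143 without the filter and 39 without the shallow MOG_L replicate 4. It was 0, 34 and 0 without ITE_MOG_L replicate 1, 2 and 4, and 45, 40, 0 and 3 without ITE_L replicate 1, 2, 3 and 4. Of 6 genes named and past the threshold, 0 stayed past it in each of the 8 fits that left out a library. Aif1 and Ccl4 did not pass without high-background libraries, nor did Aif1 with voom.

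The remaining comparisons of astrocytes lay within index sets and gave no gene past the threshold with edgeR, DESeq2 or voom. ITE_L against Plain_L had 613 genes at an unadjusted p under 0.05, and the chemokine gene Ccl6 lay at 48.3 ± 15.1 and 427 ± 563 CPM (adjusted p 0.902). Of 18 cell cycle genes 0 rose over all genes and 5 adjusted over the list alone (median 1.14, adjusted p 0.000245, and adjusted p = 0.526 with an estimated correlation). Plain_L against Vehicle had 1131 genes at an unadjusted p under 0.05. Of 17 genes of homeostatic microglia 0 fell over all genes and 9 adjusted over the list alone there (median -1.44, adjusted p 4.30e-10, and adjusted p = 0.0937 with an estimated correlation). The sum of microglia markers was 1039 ± 816 CPM in Plain_L and 3643 ± 1575 in Vehicle, and that of monocyte and macrophage markers 3215 ± 3002 and 4839 ± 1867. ITE_MOG_L against MOG_L had 108 such genes, and the collagen gene Col1a2 was among the 5 with the smallest p (adjusted p 1). Without the filter on low counts the comparisons of ITE_L with Plain_L and Plain_L with Vehicle gave 7 and 2 genes.

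In microglia, ITE_MOG_L against Plain_L lowered 4 genes and raised none. Fibronectin (Fn1), a matrix gene, fell from 81.4 ± 43.9 to 11.4 ± 3.72 CPM (log2 fold change -2.89, SE 0.469, adjusted p 0.00376, n = 4 each), Lilr4b, a leukocyte receptor gene of a family with shared reads, from 61.3 ± 30.5 to 9.52 ± 2.53 (log2 fold change -2.71, SE 0.419, adjusted p 0.00266), Cybb from 122 ± 44.8 to 40.2 ± 11.9 (-1.67, adjusted p 0.014) and the acute-phase gene Saa3, also of such a family, from 63.7 ± 56.4 to 2.7 ± 3.58 (-4.63, adjusted p 0.0443). The microglial gene Fcrls lay at 375 ± 180.4 against 101 ± 58.5 CPM, Clec7a at 51.3 ± 13.1 against 158 ± 106 and Tnf at 405 ± 132 against 206 ± 135 (adjusted p 0.0783, 0.0783 and 0.405). Of 17 genes of homeostatic microglia 0 rose over all genes and 11 adjusted over the list alone (median 0.98, adjusted p 4.78e-13, and adjusted p = 0.334 with an estimated correlation). Of 33 interferon-stimulated genes 0 fell over all genes and 8 adjusted over the list alone (median -0.93, adjusted p 5.04e-08, and adjusted p = 0.541 with an estimated correlation). Microglia markers summed to 33033 ± 5668 CPM in ITE_MOG_L and 15899.9 ± 11235 in Plain_L, and monocyte and macrophage markers to 939 ± 74.1 and 3163 ± 3098. Within Plain_L the microglia markers lay at 2596 and 10600 CPM in the high-background replicates 1 and 3 and at 25710 and 24700 in replicates 2 and 4. The monocyte and macrophage markers lay at 422 and 7578 CPM in replicates 1 and 3 and at 2757 and 1892 in replicates 2 and 4.

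For ITE_MOG_L against Plain_L in microglia, groups did not overlap in 4 of the 4 genes (over all tested genes the share was 5.41%, and chance gives 2.86%). The count was 60 with DESeq2, 1 in a fit of the 2 groups alone, 48 without the filter and 8 without high-background libraries. It was 14, 8 and 28 without Plain_L replicate 1, 2 and 4, and 2 and 1 without ITE_MOG_L replicate 1 and 3. Of the 4 genes, only Lilr4b stayed past the threshold in each of the 8 fits that left out a library of the 2 groups. Lilr4b and Cybb did not pass in a fit of the 2 groups alone, Cybb without the filter, Fn1 and Saa3 with voom, or Saa3 without high-background libraries. The median log2 fold change was -0.49 over all genes with a count in DESeq2 and -0.03 over the filtered genes with TMM, which are different sets of genes.

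Against Vehicle, ITE_MOG_L changed 1 gene in microglia: Fn1 fell from 70 ± 37.1 CPM (log2 fold change -2.58, SE 0.464, adjusted p 0.042, n = 4 each). The complement gene C3 lay at 22.7 ± 9.02 against 71.5 ± 13.8 CPM and Axl, a receptor for apoptotic cells, at 121 ± 32.6 against 291 ± 24.6 (adjusted p 0.122 and 0.173). Of 23 genes of disease-associated microglia 0 fell over all genes and 10 adjusted over the list alone (median -0.78, adjusted p 2.31e-13, and adjusted p = 0.311 with an estimated correlation). Microglia markers summed to 33033 ± 5668 CPM in ITE_MOG_L and 24898 ± 4224 in Vehicle, and monocyte and macrophage markers to 939 ± 74.1 and 2342 ± 1114. Groups did not overlap in this 1 gene (over all tested genes the share was 5.93%, and chance gives 2.86%). The count was 0 with RLE scaling, 4 with DESeq2, 20 with voom, 40 in a fit of the 2 groups alone, 11 without the filter and 38 without high-background libraries. It was 0 without Vehicle replicate 1 and 0, 0, 0 and 0 without ITE_MOG_L replicate 1, 2, 3 and 4.

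MOG_L against Plain_L, within an index set, lowered 8 genes in microglia and raised none. The matrix gene Spon1 fell from 41.7 ± 7.95 to 6.73 ± 1.54 CPM (log2 fold change -2.6, SE 0.487, adjusted p 0.0146, n = 4 each), the immune receptor gene Cd244a from 57.1 ± 20.9 to 8.87 ± 5.17 (-2.62, adjusted p 0.0146) and Saa3 to 1.57 ± 1.77 (-5.3, adjusted p 0.0146). Among lists, of 17 genes of homeostatic microglia 0 rose over all genes and 10 adjusted over the list alone (median 1, adjusted p 4.78e-13, and adjusted p = 0.334 with an estimated correlation). The sum of microglia markers was 33831 ± 4248 CPM in MOG_L and 15899.9 ± 11235 in Plain_L, and that of monocyte and macrophage markers 1224 ± 228 and 3163 ± 3098. The microglia markers of Plain_L were lowest in its high-background replicates 1 and 3. Its monocyte and macrophage markers stood at 7578 CPM in replicate 3 and at 422 to 2757 in the others. Groups did not overlap in 7 of the 8 genes (over all tested genes the share was 5.95%, and chance gives 2.86%). The count was 141 with DESeq2, 0 in a fit of the 2 groups alone, 35 without the filter and 13 without high-background libraries. It was 0, 0, 0 and 1 without MOG_L replicate 1, 2, 3 and 4, and 18, 86, 4 and 26 without Plain_L replicate 1, 2, 3 and 4. Of 6 genes named and past the threshold, 0 stayed past it in each of the 8 fits that left out a library. Cd244a and Saa3 did not pass without high-background libraries, where Spon1 did. Spon1 and Cd244a did not pass without the filter, nor did Saa3 with voom. The median log2 fold change was -0.54 over all genes with a count in DESeq2 and -0.02 over the filtered genes with TMM, which are different sets of genes.

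The other comparisons of microglia gave no gene past the threshold with edgeR. ITE_L against Plain_L had 267 genes at an unadjusted p under 0.05 and 0 and 0 with DESeq2 and voom, and Saa3 lay at 5.69 ± 1.35 and 63.7 ± 56.4 CPM (adjusted p 1). Plain_L against Vehicle had 926 and 0 and 0 with these tools, 5 without the filter and 1 without high-background libraries. ITE_MOG_L against ITE_L had 1169, with 24 by DESeq2, 0 by voom, 73 without the filter, 5 without high-background libraries and 84 without ITE_L replicate 4. The chemokine gene Ccl22 lay at 9 ± 4.47 against 52.4 ± 12.8 CPM there (adjusted p 0.228). ITE_MOG_L against MOG_L had 142, with 0 by DESeq2, 1 by voom and 2 without the filter.

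In monocytes, ITE_MOG_L against Plain_L lowered 45 genes and raised 11. Clec4d, a lectin gene of a family with shared reads, fell from 128 ± 101 to 8.98 ± 4.74 CPM (log2 fold change -3.7, SE 0.579, adjusted p 0.00557, n = 4 each), the coagulation factor gene F10 from 349 ± 243 to 27.3 ± 22.6 (-3.61, adjusted p 0.0114), the protease inhibitor gene Slpi from 275 ± 197 to 24.3 ± 11 (-3.49, adjusted p 0.0114) and the lipid droplet gene Hilpda from 396 ± 396 to 36.8 ± 14.2 (-3.37, adjusted p 0.0114). The chemokine gene Ccl2, which draws monocytes into tissue, fell from 381 ± 276 to 78.4 ± 61.1 CPM (-2.23, adjusted p 0.0463) and the fatty acid carrier gene Fabp5 from 379.6 ± 224 to 75.7 ± 35.1 (-2.31, adjusted p 0.0146). Serpinf1, a secreted anti-angiogenic gene, rose from 38.8 ± 11.5 to 208 ± 102 CPM (log2 fold change 2.44, SE 0.437, adjusted p 0.0113), the iron exporter gene Slc40a1 from 18.5 ± 5.12 to 65.9 ± 19.3 (1.84, adjusted p 0.0222) and Sall1, a transcription factor of microglia, from 36.6 ± 15.2 to 107 ± 23.3 (1.54, adjusted p 0.0366).

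Of 20 antigen presentation genes 0 fell over all genes and 0 adjusted over the list alone in monocytes of ITE_MOG_L against Plain_L (median -0.9, adjusted p 1.38e-08, and adjusted p = 0.396 with an estimated correlation). Of 14 chemokine receptor and adhesion genes 2 fell over all genes and 4 adjusted over the list alone (median -0.69, adjusted p 0.000685, and adjusted p = 0.396 with an estimated correlation). Of 18 glycolysis genes 0 fell over all genes and 5 adjusted over the list alone (median -0.84, adjusted p 8.59e-05, and adjusted p = 0.396 with an estimated correlation). Of 17 genes of homeostatic microglia 1 rose over all genes and 3 adjusted over the list alone (median 0.68, adjusted p 0.000141, and adjusted p = 0.417 with an estimated correlation). Microglia markers summed to 12879 ± 6965 CPM in ITE_MOG_L and 7553 ± 2981 in Plain_L, and monocyte and macrophage markers to 11218 ± 6816 and 27241 ± 18409.6. The high-background ITE_MOG_L replicate 3 lay low in both, at 2622 and 2596 CPM. Plain_L replicate 3 stood at 54360 CPM for monocyte and macrophage markers, and the other Plain_L libraries at 14000 to 22460.

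For ITE_MOG_L against Plain_L in monocytes 56 genes passed the threshold, 11 higher and 45 lower, and 47 had groups that did not overlap (over all tested genes the share was 6.83%, and chance gives 2.86%). DESeq2 gave 485, of which 295 were higher. Its median log2 fold change was 0.83 over all genes with a count, against 0.08 over the filtered genes with TMM. These medians cover different genes, so their gap cannot be put down to scaling alone. The count was 2 with voom, 0 in a fit of the 2 groups alone, 130 without the filter, 162 without the shallow Vehicle replicate 2 and 111 without high-background libraries. It was 15 and 16 without Plain_L replicate 2 and 3, and 17, 137, 24 and 175 without ITE_MOG_L replicate 1, 2, 3 and 4. Of 25 genes named and past the threshold, only Clec4d stayed past the threshold in each of the 8 fits that left out a library of the 2 groups. F10, Slpi and Ccl2 did not pass without high-background libraries, and Slc40a1 and Sall1 did not without the filter. Clec4d, Hilpda, Fabp5 and Serpinf1 passed in both of these fits.

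**Figure D3:**
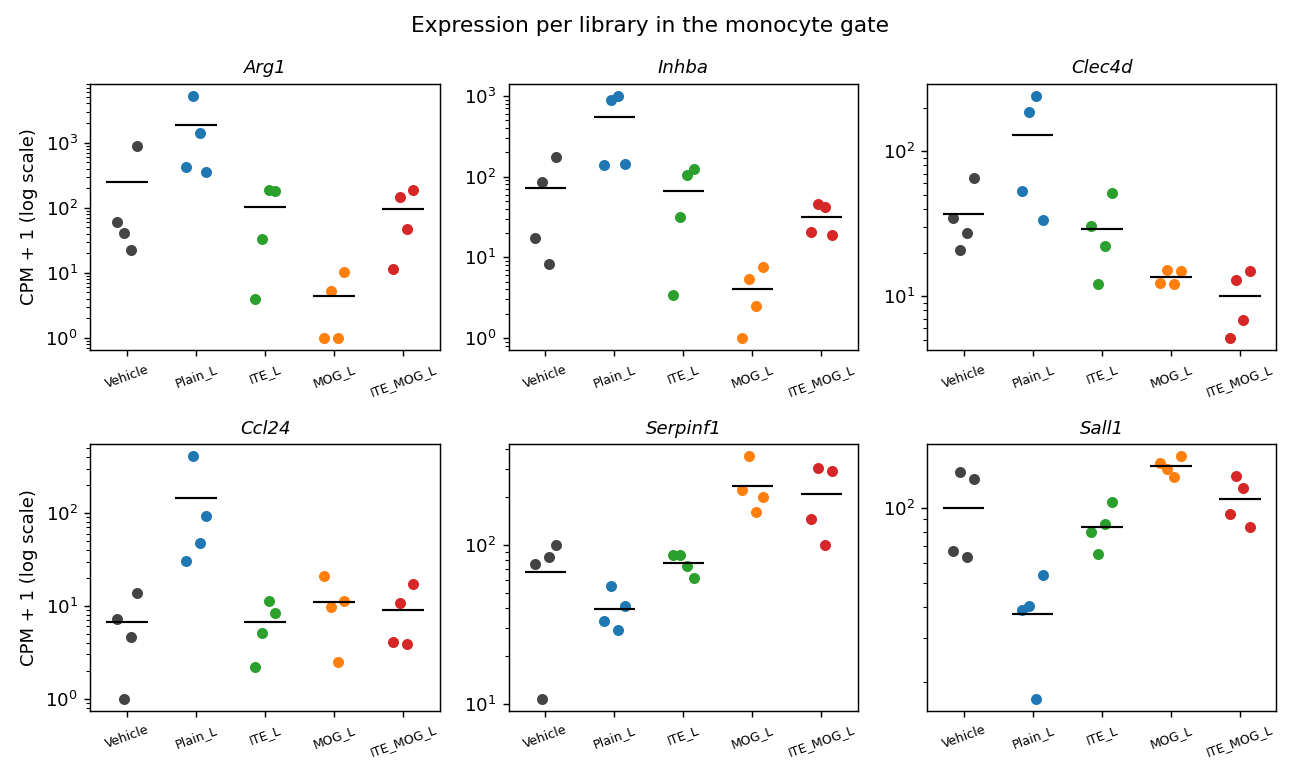
CPM + 1 on a log axis for 6 genes in monocyte libraries of the 5 treatments, 1 point per library, lines at the mean of 4. Arg1 averaged 1859 CPM in Plain_L and 3.41 in MOG_L, and Serpinf1 38.8 in Plain_L and 208 in ITE_MOG_L.

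MOG_L against Plain_L lowered 46 genes in monocytes and raised 27. Arginase (Arg1), an enzyme of alternatively activated macrophages, fell from 1859 ± 2319 to 3.41 ± 4.43 CPM (log2 fold change -9.1, SE 1.93, adjusted p 0.0413, n = 4 each), the activin subunit gene Inhba from 543 ± 466 to 3.08 ± 2.91 (log2 fold change -7.44, SE 1.31, adjusted p 0.0107) and the interleukin-12 subunit gene Il12a from 21.9 ± 12.2 to 0.271 ± 0.541 (-5.96, adjusted p 0.0304). Cd300e, a receptor gene of monocytes from a family with shared reads, rose from 3.05 ± 2.63 to 68.5 ± 25.4 CPM (log2 fold change 4.42, SE 0.714, adjusted p 0.00329) and Treml4, another myeloid receptor gene, from 16.1 ± 4.05 to 112 ± 49.6 (2.79, adjusted p 0.008). The microglial genes Fcrls, Slc2a5 and Sall1 rose by 2.72, 2.28 and 2, Sall1 from 36.6 ± 15.2 to 146 ± 12 CPM. Among lists, of 17 genes of homeostatic microglia 3 rose over all genes and 13 adjusted over the list alone (median 1.36, adjusted p 1.99e-19, and adjusted p = 0.177 with an estimated correlation). The sum of microglia markers was 18705 ± 3899 CPM in MOG_L and 7553 ± 2981 in Plain_L, and that of monocyte and macrophage markers 13195 ± 946 and 27241 ± 18409.6. Plain_L replicate 3 stood at 54360 CPM for the latter and the other Plain_L libraries at 14000 to 22460.

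For MOG_L against Plain_L in monocytes 73 genes passed the threshold, 27 higher and 46 lower, and 72 had groups that did not overlap (over all tested genes the share was 7.67%, and chance gives 2.86%). The count was 201 with DESeq2, 272 with voom, 207 in a fit of the 2 groups alone and 234 without high-background libraries. It was 26 and 12 without Plain_L replicate 2 and 3, and 24, 11, 23 and 26 without MOG_L replicate 1, 2, 3 and 4. Of 16 genes named and past the threshold, only Cd300e and Saa3 stayed past it in each of the 8 fits that left out a library of the 2 groups, while Arg1 stayed in 1 of 8 such fits and Inhba in 5 of 8. Arg1 and Inhba did not pass with voom, nor did Arg1 without the filter, while 8 of the 16 stayed in every other setting.

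ITE_L against Plain_L changed 1 gene in monocytes: Ccl24, a chemokine gene for eosinophils, fell from 143 ± 177 to 5.7 ± 3.9 CPM (log2 fold change -4.65, SE 0.787, adjusted p 0.0274, n = 4 each). Hilpda lay at 60.9 ± 4.99 against 396 ± 396 CPM (adjusted p 0.306). Among lists, of 17 genes of homeostatic microglia 0 rose over all genes and 3 adjusted over the list alone (median 0.87, adjusted p 7.24e-12, and adjusted p = 0.244 with an estimated correlation). The sum of microglia markers was 13840.4 ± 2441 CPM in ITE_L and 7553 ± 2981 in Plain_L, and that of monocyte and macrophage markers 16872 ± 3927 and 27241 ± 18409.6, with Plain_L replicate 3 at 54360. The count was 19 with DESeq2, 2 with voom, 23 without the filter, and 0 in a fit of the 2 groups alone, without the shallow Vehicle replicate 2 or without high-background libraries. It was 2, 0 and 7 without Plain_L replicate 1, 2 and 4, and 0, 0, 2 and 0 without ITE_L replicate 1, 2, 3 and 4. These counts include other genes: Ccl24 stayed past the threshold in 4 of 8 fits that left out a library of the 2 groups, did not pass with voom and had no adjusted p with DESeq2.

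The other comparisons of monocytes gave no gene past the threshold with edgeR. ITE_MOG_L against Vehicle had 620 genes at an unadjusted p under 0.05, 1 by DESeq2, 0 by voom and 7 without the filter. Of 20 antigen presentation genes 0 fell over all genes and 0 adjusted over the list alone there (median -0.5, adjusted p 2.66e-05, and adjusted p = 0.441 with an estimated correlation). Plain_L against Vehicle, within an index set, had 690, 9 by DESeq2, 1 by voom, 20 without the filter, and 2, 4 and 1 without Vehicle replicate 4, Plain_L replicate 1 and Plain_L replicate 3. Ccl24 lay at 5.66 ± 5.4 CPM in Vehicle (adjusted p 0.107 against Plain_L).

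Within an index set, ITE_MOG_L against ITE_L and against MOG_L gave no gene in monocytes with edgeR. The adhesion gene Vcam1 lay at 38.4 ± 19.6 CPM in ITE_MOG_L and 155 ± 59.8 in ITE_L (adjusted p 0.444), and the cell cycle gene Mad2l1 at 48.6 ± 36.1 and 6.66 ± 3.01 (adjusted p 0.301). Against ITE_L 923 genes had an unadjusted p under 0.05, with 1 by DESeq2, 0 by voom, 10 without the filter, 1 without high-background libraries and 3, 1 and 1 without ITE_L replicate 2, ITE_L replicate 3 and ITE_MOG_L replicate 2. Against MOG_L there were 968, with 14 by DESeq2, 0 by voom and 1 without the filter.

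Genes around the aryl hydrocarbon receptor, which ITE binds, showed few differences between ITE_MOG_L and Plain_L. Of 5 measured targets in astrocytes 0 passed, and 0 adjusted over the list alone (list adjusted p 0.773). Tiparp, a target gene that feeds back on the receptor, fell in monocytes from 187 ± 75.7 to 65.7 ± 24.5 CPM (log2 fold change -1.51, SE 0.346, adjusted p 0.038) and lay at 122 ± 35.8 in Vehicle (adjusted p 0.918 for ITE_MOG_L against Vehicle). The fall stayed past the threshold in 3 of 8 fits that left out a library of the 2 groups (adjusted p up to 0.203), and did not without the filter, in a fit of the 2 groups alone or with voom. The receptor gene Ahr lay at 20.3 ± 16.7 and 16.4 ± 12.2 CPM in monocytes of ITE_MOG_L and Plain_L (adjusted p 0.902). Cyp1a1, the classical target, and Il10 had too few counts to be tested in any cell type.

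No gene differed between cell types in its response to ITE_MOG_L against Plain_L with edgeR. Microglia against astrocytes had 551 genes at an unadjusted p under 0.05, with 31 past the threshold by DESeq2, 0 by voom and 18 without high-background libraries. Monocytes against astrocytes had 1206, with 14 by DESeq2, 1 by voom, 3 without the filter, and 3, 1 and 1 without monocyte Plain_L replicate 1, Plain_L replicate 4 and ITE_MOG_L replicate 3. Monocytes against microglia had 1648, with 497 by DESeq2, 0 by voom, 50 without the filter, and 2 and 333 without monocyte ITE_MOG_L replicate 2 and 4. In simulated data of monocytes and astrocytes the step recovered 7.19% of 4-fold differences in response, so most such differences between these 2 cell types would go unseen. The contrasts with microglia were not simulated.

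**Figure D4:**
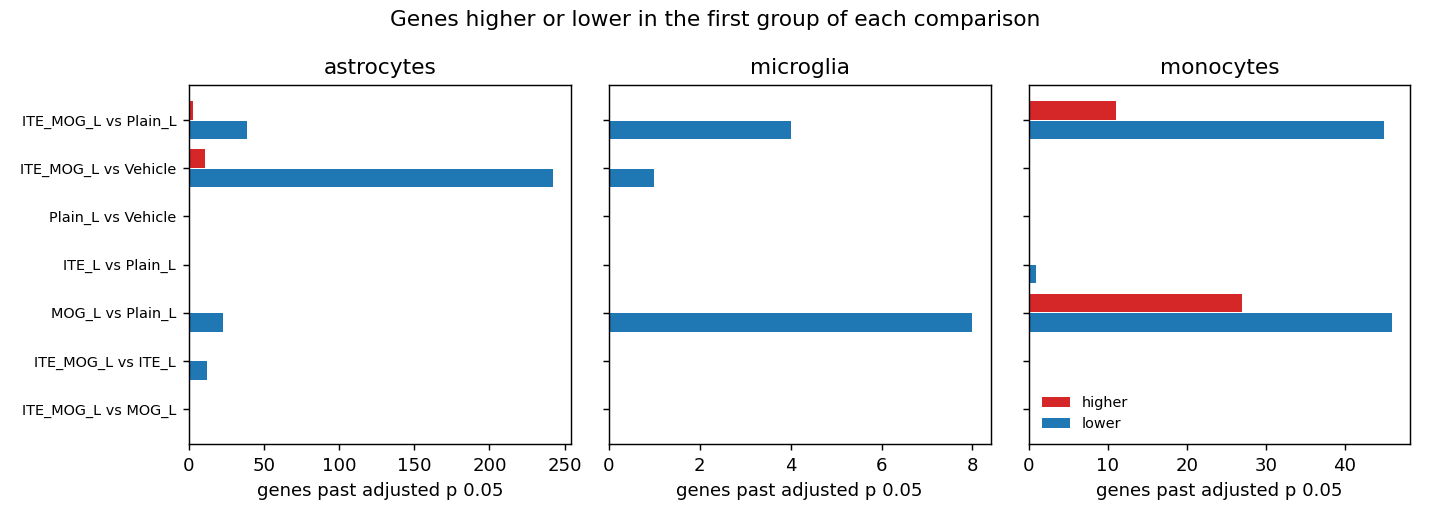
Genes past an adjusted p of 0.05 in each of the 7 comparisons of each cell type, higher and lower in the first-named group. The longest bar is the 242 genes lower in ITE_MOG_L than in Vehicle astrocytes.

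Across the gene lists, 137 of 280 pairs of a list and a comparison passed in astrocytes, 67 of 259 in microglia and 99 of 266 in monocytes. With an estimated correlation 30, 0 and 0 passed, and those of astrocytes came from ITE_MOG_L against Plain_L, Vehicle and ITE_L and from MOG_L against Plain_L. In GRCm38 the genes lie as follows: Grin2c on chromosome 11 from 115249169 to 115267243, Clec7a on chromosome 6 from 129461591 to 129472779, Il1b on chromosome 2 from 129364570 to 129371139 and Itgb2 on chromosome 10 from 77530252 to 77565708. Further, Fn1 on chromosome 1 from 71585520 to 71653200, Lilr4b on chromosome 10 from 51480632 to 51486703, Clec4d on chromosome 6 from 123262111 to 123275265, Serpinf1 on chromosome 11 from 75409769 to 75422701, Arg1 on chromosome 10 from 24915221 to 24927484 and Cd300e on chromosome 11 from 115051917 to 115062177.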

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

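The tests of background libraries, and those of the astrocyte and microglia patterns below, were chosen after the results had been seen; the tests of the monocyte pattern and the counts of other splits were written before. Of 215 groups of 4 libraries, 15 held a library far from the other 3, and chance gives about 1 in 20, or 10.8 here.

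Among library properties, the total count of astrocyte MOG_L replicate 4 was 129500 against 766400 to 886900 in the other libraries of its group. Background on receptor genes stood out in the same library (4.83 against 0.396 to 0.629 CPM per kb), in astrocyte ITE_MOG_L replicate 3 (4.26 against 0.535 to 0.908) and in monocyte Vehicle replicate 2 (3.28 against 0.251 to 0.552). In this last library the monocyte and macrophage markers summed to 3833 against 20070 to 21220 CPM in the others.

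Among genes of astrocytes in ITE_MOG_L, replicate 3 stood apart for Dlgap1 (119 against 60.2 to 68.6 CPM), S100a9 (41.5 against 3.89 to 4.9) and Spp1 (11.9 against 48.6 to 54), replicate 4 for Cxcl13 (3.89 against 0 to 0) and replicate 2 for C1qa (104 against 30.4 to 41.5) and H2-Aa (166 against 5.93 to 27.2). In monocytes F10 stood apart in ITE_MOG_L replicate 2 (61 against 14 to 19.8 CPM), Ccl24 in Plain_L replicate 2 (405 against 29.1 to 92.3), Il12a in MOG_L replicate 2 (1.08 against 0 to 0) and Cd300e in Plain_L replicate 4 (6.98 against 1.61 to 1.97).

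The falls in astrocyte libraries of ITE_MOG_L against Vehicle held mostly myeloid genes: 95.9% of them were at least 4 times higher in microglia or monocyte libraries than in the mean of all astrocyte libraries, against 5.05% of tested genes. High background is argued against, since 223 of the 242 falls were kept without those libraries. Less RNA of myeloid cells in the astrocyte gate stays open: 100% of 24 abundant microglial genes were lower, with a median of -3.25 (quartiles -3.69 to -2.78) near the -3.02 of the falls, and sorting may have left less of it in this group. A first definition of myeloid genes, set against the ITE_MOG_L libraries themselves, gave 100% against 6.77% and 199 abundant genes, and was replaced after its result was seen because it was circular. The set of second indexes cannot be told apart from the treatment, as 0 comparisons of a MOG-loaded with an unloaded group lie within a set, and fewer myeloid cells in the tissue was not tested.

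In monocytes, MOG_L against Plain_L gave 46 falls, Arg1 and Inhba among them, and 27 rises, Fcrls and Sall1 among them. The set of second indexes is argued against: between ITE_L and Vehicle, across the sets, the 73 genes moved by a median of 0.13 in the direction seen, with 44 of them in that direction, where MOG_L against Plain_L gave 2.5. Which of the 2 groups stood apart stays open. In that direction the genes moved by 1.36 in Vehicle against Plain_L (72 of them), within a set, and by 1.44 in ITE_L against Plain_L (73), against 1.06 in MOG_L against ITE_L (72), within a set, and 1.05 in MOG_L against Vehicle (72). These 4 comparisons reuse libraries by which the genes were chosen, so they lean in that direction. ITE_MOG_L against ITE_L, within a set and with none of those libraries, gave 0.67 (63). More microglia in the monocyte gate stays open for the falls, since 53 monocyte-enriched genes had a median of -1.01 (quartiles -1.59 to -0.45), just past the -1 set beforehand. The falls had a median of -2.81, but they were chosen by their change in this comparison, so the gap does not limit this explanation. For the rises, more microglia in the gate cannot be told apart from a change in expression, with 567 microglia-enriched genes at a median of 0.61 (quartiles 0.15 to 1.1) and the rises at 1.99.

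In microglia the MOG load, taken over all 4 liposome groups, changed 443 genes, and high background is a candidate explanation for part of the change. Of 175 tested genes of the receptor families used to measure background, 171 were lower with the load, and 19 were among the 362 falls. These genes define the background, and the high-background libraries of microglia carry no MOG load. Their lower values with the load thus restate that measure and add no support for the explanation. Without high-background libraries 49 genes passed, of which 32 were among the 443. All 4 high-background libraries of microglia belong to Plain_L and ITE_L. Of the first genes 320 were still tested, and their median log2 fold change, in the direction first seen, went from 1.4 (quartiles 1.07 to 1.82) to 0.71 (quartiles 0.45 to 1.15), with a median SE of 0.345 and 0.363, so calls ended mainly because folds shrank. Each of the 35 other ways of leaving out 2 Plain_L and 2 ITE_L libraries left a larger median, from 0.94 to 2.1. These medians cover different genes, 350 to 443 of the first ones, and started higher, from 1.47 to 1.69. The nearest went from 1.47 to 0.94 over 350 genes and left out 3 high-background libraries. The count alone is less telling. It ran from 8 to 7099 over the 35 other ways and was as low in 9, each of which left out at least 2 high-background libraries. 316 of the 320 genes kept their direction, so a smaller change with the load stays open.

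Other splits of the same libraries show how often as large a count arises by chance. The smallest possible share is 1 of 35 splits, and shares were not corrected for the number of comparisons. Such a share speaks against chance only for a comparison taken alone. Chance stays open where only 1 or 4 genes passed. These are ITE_MOG_L against Vehicle and against Plain_L in microglia, and ITE_L against Plain_L in monocytes. Simulated data of ITE_MOG_L against Plain_L gave 1 false call in microglia and 2 in monocytes, but these data also held truly changed genes. Plain_L against Vehicle, simulated with no change, gave 0 false calls in each cell type. With 1 simulated data set per cell type, this does not decide how often so few calls arise by chance. In astrocytes the splits that gave as many genes were 2 of 35 for ITE_MOG_L against Plain_L (real 42, highest other 50), 1 of 35 for ITE_MOG_L against Vehicle (real 253, highest other 1), 35 of 35 for Plain_L against Vehicle (real 0, highest other 0), 35 of 35 for ITE_L against Plain_L (real 0, highest other 0), 4 of 35 for MOG_L against Plain_L (real 23, highest other 703), 2 of 35 for ITE_MOG_L against ITE_L (real 12, highest other 14) and 35 of 35 for ITE_MOG_L against MOG_L (real 0, highest other 0). The highest other split for MOG_L against Plain_L puts Plain_L replicate 1 with MOG_L replicates 1 to 3, against the 3 high-background libraries and Plain_L replicate 2, whose background was low (0.558 CPM per kb, against 0.622 in replicate 1), so it does not part the libraries by background alone.

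In microglia they were 1 of 35 for ITE_MOG_L against Plain_L (real 4, highest other 3), 1 of 35 for ITE_MOG_L against Vehicle (real 1, highest other 0), 35 of 35 for Plain_L against Vehicle (real 0, highest other 0), 35 of 35 for ITE_L against Plain_L (real 0, highest other 2963), 2 of 35 for MOG_L against Plain_L (real 8, highest other 50), 35 of 35 for ITE_MOG_L against ITE_L (real 0, highest other 0) and 35 of 35 for ITE_MOG_L against MOG_L (real 0, highest other 10). The highest other split for ITE_L against Plain_L parts the 4 high-background libraries from the others, which points to a structure of the samples other than treatment. These 4 libraries also had lower total counts than the others of the 2 groups, so background and depth cannot be told apart here.

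In monocytes they were 1 of 35 for ITE_MOG_L against Plain_L (real 56, highest other 7), 35 of 35 for ITE_MOG_L against Vehicle (real 0, highest other 534), 35 of 35 for Plain_L against Vehicle (real 0, highest other 1), 1 of 35 for ITE_L against Plain_L (real 1, highest other 0), 1 of 35 for MOG_L against Plain_L (real 73, highest other 0), 35 of 35 for ITE_MOG_L against ITE_L (real 0, highest other 0) and 35 of 35 for ITE_MOG_L against MOG_L (real 0, highest other 1). A split that calls many genes where the real one calls 0, as for ITE_MOG_L against Vehicle, points to a structure of the samples other than treatment.

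For the differences between cell types, 100 of 100 (real 0, highest other 67) drawn splits gave as many genes for microglia against astrocytes, 100 of 100 (real 0, highest other 178) for monocytes against astrocytes and 100 of 100 (real 0, highest other 0) for monocytes against microglia. For the gene lists it was 1 of 50 (real 137, highest other 136) in astrocytes, 15 of 50 (real 67, highest other 84) in microglia and 1 of 50 (real 99, highest other 90) in monocytes, and with an estimated correlation 1 of 50 (real 30, highest other 0), 50 of 50 (real 0, highest other 0) and 50 of 50 (real 0, highest other 1). A share of 1 of 50 is the smallest possible, and these shares were not corrected for the number of tests. Each speaks against chance only for the number of lists in a test taken alone. At the preset correlation other splits came close, with 136 against 137 in astrocytes and 90 against 99 in monocytes, so chance is not excluded there. A typical other split passed many lists too, with a median of 86 in astrocytes and 48 in monocytes. No single list is thus set apart from chance.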

How the results depend on the processing

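The fits without high-background libraries were chosen after the data had been seen; the other alternatives were fixed before the data were examined. Counts of the pairwise comparisons, of the differences between cell types and of the gene lists that are not given here stayed within 1.5 times the reported count. The cause of the changes was not tested.

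In astrocytes the number of genes past the threshold depended on the processing. Without the filter on low counts it was 114 for ITE_MOG_L against Plain_L, 2 for Plain_L against Vehicle, 7 for ITE_L against Plain_L, 97 for MOG_L against Plain_L and 143 for ITE_MOG_L against ITE_L. With DESeq2 it was 195 for ITE_MOG_L against Plain_L, 89 for MOG_L against Plain_L and 96 for ITE_MOG_L against ITE_L. With the 2 groups alone it was 0 for ITE_MOG_L against Plain_L, 0 for MOG_L against Plain_L and 26 for ITE_MOG_L against ITE_L. With voom it was 0 for ITE_MOG_L against Plain_L and 30 for ITE_MOG_L against ITE_L. Without shallow libraries it was 101 for ITE_MOG_L against Plain_L, 6 for MOG_L against Plain_L and 39 for ITE_MOG_L against ITE_L. Without high-background libraries it was 81 for ITE_MOG_L against Plain_L and 388 for ITE_MOG_L against Vehicle. Leaving out each library of the compared groups in turn gave 0 to 111 for ITE_MOG_L against Plain_L, 131 to 260 for ITE_MOG_L against Vehicle, 0 to 0 for Plain_L against Vehicle, 0 to 0 for ITE_L against Plain_L, 0 to 87 for MOG_L against Plain_L, 0 to 45 for ITE_MOG_L against ITE_L and 0 to 0 for ITE_MOG_L against MOG_L.

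In microglia the counts were small and moved with the tool. Without the filter on low counts it was 48 for ITE_MOG_L against Plain_L, 11 for ITE_MOG_L against Vehicle, 5 for Plain_L against Vehicle, 9 for ITE_L against Plain_L, 35 for MOG_L against Plain_L, 73 for ITE_MOG_L against ITE_L and 2 for ITE_MOG_L against MOG_L. With DESeq2 it was 60 for ITE_MOG_L against Plain_L, 4 for ITE_MOG_L against Vehicle, 141 for MOG_L against Plain_L and 24 for ITE_MOG_L against ITE_L. With the 2 groups alone it was 1 for ITE_MOG_L against Plain_L, 40 for ITE_MOG_L against Vehicle and 0 for MOG_L against Plain_L. With voom it was 20 for ITE_MOG_L against Vehicle and 1 for ITE_MOG_L against MOG_L. Without high-background libraries it was 8 for ITE_MOG_L against Plain_L, 38 for ITE_MOG_L against Vehicle, 1 for Plain_L against Vehicle, 13 for MOG_L against Plain_L and 5 for ITE_MOG_L against ITE_L. With RLE scaling it was 0 for ITE_MOG_L against Vehicle. Leaving out each library of the compared groups in turn gave 1 to 28 for ITE_MOG_L against Plain_L, 0 to 1 for ITE_MOG_L against Vehicle, 0 to 0 for Plain_L against Vehicle, 0 to 0 for ITE_L against Plain_L, 0 to 86 for MOG_L against Plain_L, 0 to 84 for ITE_MOG_L against ITE_L and 0 to 0 for ITE_MOG_L against MOG_L.

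In monocytes the counts moved with the tool and the groups fitted. Without the filter on low counts it was 130 for ITE_MOG_L against Plain_L, 7 for ITE_MOG_L against Vehicle, 20 for Plain_L against Vehicle, 23 for ITE_L against Plain_L, 10 for ITE_MOG_L against ITE_L and 1 for ITE_MOG_L against MOG_L. With DESeq2 it was 485 for ITE_MOG_L against Plain_L, 1 for ITE_MOG_L against Vehicle, 9 for Plain_L against Vehicle, 19 for ITE_L against Plain_L, 201 for MOG_L against Plain_L, 1 for ITE_MOG_L against ITE_L and 14 for ITE_MOG_L against MOG_L. With the 2 groups alone it was 0 for ITE_MOG_L against Plain_L, 0 for ITE_L against Plain_L and 207 for MOG_L against Plain_L. With voom it was 2 for ITE_MOG_L against Plain_L, 1 for Plain_L against Vehicle, 2 for ITE_L against Plain_L and 272 for MOG_L against Plain_L. Without shallow libraries it was 162 for ITE_MOG_L against Plain_L and 0 for ITE_L against Plain_L. Without high-background libraries it was 111 for ITE_MOG_L against Plain_L, 0 for ITE_L against Plain_L, 234 for MOG_L against Plain_L and 1 for ITE_MOG_L against ITE_L. Leaving out each library of the compared groups in turn gave 15 to 175 for ITE_MOG_L against Plain_L, 0 to 0 for ITE_MOG_L against Vehicle, 0 to 4 for Plain_L against Vehicle, 0 to 7 for ITE_L against Plain_L, 11 to 77 for MOG_L against Plain_L, 0 to 3 for ITE_MOG_L against ITE_L and 0 to 0 for ITE_MOG_L against MOG_L.

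For the differences between cell types DESeq2 gave 31 genes for microglia against astrocytes, 14 for monocytes against astrocytes and 497 for monocytes against microglia. Voom gave 1 for monocytes against astrocytes, and the fit without the filter 3 there and 50 for monocytes against microglia. Without high-background libraries microglia against astrocytes gave 18. Leaving out each library gave 0 to 0, 0 to 3 and 0 to 333.

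Gene lists depended most on the correlation between genes. With an estimated correlation 30 pairs of a list and a comparison passed in astrocytes, 0 in microglia and 0 in monocytes, with fry 35, 11 and 4, and with an estimated correlation and no high-background libraries 17, 0 and 8. Without the filter 152 passed in monocytes. Leaving out each library gave 128 to 149, 62 to 83 and 80 to 121. The list of oxidative phosphorylation reversed in astrocytes: for ITE_MOG_L against MOG_L its median was 0.07, and -0.24 without shallow libraries, which is the fit without MOG_L replicate 4, with -0.25 to 0.35 over the fits that left out a library, and for ITE_L against Plain_L it was 0.28, and -0.14 without high-background libraries.

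Of 11438 values of named genes under the alternatives, 87 changed sign and 0 of these were past the threshold in either fit. With DESeq2 115 named values newly passed and 1 no longer passed, with voom 26 and 71, and over all fits that left out a library 95 and 509. At the depth and spread of these libraries, of 100 genes changed 2-fold in simulated data, 4 were recovered in astrocytes, 11 in microglia and 6 in monocytes. Depth itself was not varied.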

Other observations

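The factorial fit below was chosen after the counts of the pairwise comparisons had been seen, and its tests of other splits were written before their results. A hypothesis is that the MOG load goes with lower values of genes shared between the cell types. The MOG load, MOG_L and ITE_MOG_L against Plain_L and ITE_L, changed 215 genes in astrocytes (191 lower), 443 in microglia (362 lower) and 64 in monocytes (48 lower). With DESeq2 it changed 343 (246 lower), 2224 (1890 lower) and 181 (114 lower). Lower in all 3 cell types were 6 genes: Saa3, Lilr4b, Hal, Wfdc17, Cd300lf and H2-M2, most of them from families with shared reads. Hal and Lilr4b were also lower in all 3 without high-background libraries, with Srgn and Lgals3. Monocytes and microglia shared 12 lower genes where chance gives 0.831 (p 7.40e-12), and 3 higher ones, Arap3, Ccr6 and Serpinf1. Without high-background libraries they shared 5 lower genes where chance gives 0.223 (p 2.48e-06), and the 3 higher ones were Arsb, Gpr34 and Serpinf1. For microglia and astrocytes the shared lower genes were 15 where chance gives 5.5 (p 0.000403), and the shared higher ones 1 where chance gives 0.11 (p 0.105), Jam2. For monocytes and astrocytes the lower ones were 10 where chance gives 0.777 (p 3.26e-09), and 0 higher ones were shared. Without high-background libraries these pairs shared 16 and 23 lower genes, with 0.985 and 2.37 by chance, and 1 and 0 higher ones. These chance values take the cell types as independent, and the labels do not say whether cell types come from the same mice. RNA shared between the gates also differed between groups and was not separated from a shared response. In Plain_L, ITE_L, MOG_L and ITE_MOG_L microglia markers summed to 7553 ± 2981, 13840.4 ± 2441, 18705 ± 3899 and 12879 ± 6965 CPM in monocyte libraries, and monocyte and macrophage markers to 3163 ± 3098, 1800.1 ± 225, 1224 ± 228 and 939 ± 74.1 in microglia libraries. Single high-background libraries weigh on these means. Monocyte ITE_MOG_L replicate 3 lay at 2622 CPM against 14430 to 17400 in the others, and microglia Plain_L replicate 3 at 7578 against 422 to 2757.

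With edgeR the ITE load changed 0 genes in each cell type, with 242, 196 and 706 genes at an unadjusted p under 0.05 in astrocytes, microglia and monocytes and 0 by DESeq2 in each. The interaction of the loads changed 0 genes with edgeR, with 348, 237 and 679 unadjusted and 0, 0 and 3 by DESeq2. A p past the threshold for one load and not for the other does not show that the loads differ, and this difference was not tested.

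Without high-background libraries the MOG load changed 456 genes in astrocytes (139 higher and 317 lower), 49 in microglia (16 and 33) and 143 in monocytes (62 and 81). The share of lower genes among those called was thus smaller in each cell type. In astrocytes and monocytes the number of lower genes itself grew, from 191 and 48, and that of higher ones grew more. Of drawn splits, 5 of 100 (real 215, highest other 1657) gave as many genes in astrocytes and 4 of 100 (real 443, highest other 1347) in microglia. The share in microglia lies just under the limit set beforehand and that in astrocytes at it. So few draws cannot separate them, and chance is not excluded in either. In monocytes 1 of 100 (real 64, highest other 1) gave as many, the smallest possible share, which speaks against chance for this count taken alone. The contrast was chosen after the pairwise counts of the same libraries had been seen, and shares were not corrected. Chance is therefore not excluded there either. The highest other splits of astrocytes and microglia call several times the real count, which points to a structure of the samples other than the load. For the ITE load the splits were 100 of 100 (real 0, highest other 756), 100 of 100 (real 0, highest other 1845) and 100 of 100 (real 0, highest other 2), and for the interaction of the loads 100 of 100 (real 0, highest other 573), 100 of 100 (real 0, highest other 504) and 100 of 100 (real 0, highest other 14). In astrocytes the MOG load and the set of second indexes cannot be told apart.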
